A study of unidentified methanotrophic bacterium with 9 samples.

How the data were processed

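The assay was an oligonucleotide microarray of 72 probes for a methanotrophic (methane-oxidising) bacterial community. It was hybridised with targets made from the genomic DNA of soil taken from 3 depths of a methane-oxidising biocover, named top, middle and bottom layer. Per the labels' protocols, DNA was extracted with a soil kit, transcribed in vitro with Cy3- or Cy5-labelled nucleotides, purified and fragmented. How the template for that transcription was amplified, which gene the probes target, the hybridisation and the scanner settings are not given in the sources used here. The deposited files hold unnormalised spot and background intensities on a linear scale, and, per the file headers, they were written by an image quantification program of version 5.6.1 with automatic spot segmentation. Per the file headers, the program also called a spot empty at a threshold of 2, and the deposited empty calls equalled a mean spot intensity below the local background mean plus 2 background SDs in 100% of the spots of every channel.

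Each layer was hybridised in Cy3 on 1 slide and in Cy5 on another, so that 3 slides formed a loop: top in Cy3 with middle in Cy5 on slide 1, middle in Cy3 with bottom in Cy5 on slide 2, and bottom in Cy3 with top in Cy5 on slide 3. Every channel held 216 spots, that is 3 subarrays of the 72 probes. The files name these subarrays replicate 1, 2 and 3 of a layer, and the labels list the same replicates as 9 samples, 3 per layer. The labelled replicates are therefore spots within slides. No source used here says whether the 2 channels of a layer came from separate DNA extracts, soil cores or labelling reactions, so p-values measure only the spread between these hybridisations, which may be technical. The 2 images of slide 1, and those of slide 3, shared all spot positions. The 2 images of slide 2 shared none and lay a median of 32 pixels apart across and -9 pixels down, so it is open whether they show 1 array. The labels list a Cy3 table for the second bottom channel, but the file used here is marked as the Cy5 image, and its median background of 101 lies next to the 112 and 114 of the other Cy5 channels and below the 191 to 210 of the Cy3 channels.

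Mean spot intensities were corrected for the median local background by normexp with an offset of 50, normalised by loess within each slide and by Aquantile between slides, and put on a log2 scale with limma 3.58.1 in R 4.3.3. The 3 spots of a probe were averaged within a channel. A probe was above the detection level in a channel when at least 2 of its 3 spots were not called empty, and it was tested when this held in both channels of at least 1 layer. Layers were compared with limma's lmFit and eBayes on the 6 channels, with dye as a covariate and Benjamini-Hochberg adjustment over the 28 tested probes of each of the 3 comparisons. The design fixed beforehand also had the slide as a random block. Layer, dye and slide together leave 0 residual degrees of freedom, so its correlation could not be estimated and the slide was dropped. Without the dye term the correlation was 0.455. The fit used had 2 residual and 12.9 prior degrees of freedom. The SE and p-value of a probe therefore rest mostly on spread pooled over the tested probes, which are not independent. A fold change is on the scale of the corrected intensity plus the offset, so changes of dim probes are understated. All values are relative within a channel and carry no absolute amount of target.

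For description, the share of a probe in the summed signal of a channel was computed per subarray from the background-subtracted intensity, with values below 0 set to 0. It was averaged over the 2 dyes of each labelled sample and is given as mean ± SD over the 3 labelled samples. This SD leaves out the spread between the 2 hybridisations of a layer, which can be larger. The Shannon index (natural logarithm) and Bray-Curtis distance were computed on the shares of normexp-corrected intensities, without the offset. The precision of all values is limited by the number of arrays.

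The files number the probes 1 to 72 and do not pair the numbers with names, sequences or target organisms. The 12 probe lists fixed beforehand by name (genera of methanotrophs, ammonia oxidisers, controls) therefore matched 0 probes and were not tested, nor was scaling to control probes. The rule for named probes was also fixed beforehand: the largest absolute log2 differences among probes past the threshold whose channel values did not overlap between layers. It was limited to at most 2 probe numbers in each direction per comparison because the numbers carry no names. Probes 2 and 47 are also named, as the brightest, and were chosen after their values were seen.

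The alternatives were other background corrections, scalings, detection filters, model terms, spot averages, the 3 labelled replicates as samples, and leaving out each channel. These choices were made before the data were examined, with 5 exceptions chosen afterwards: the need for 2 of 3 spots above the detection level, the removal of the slide from the fit, the limit on probe numbers given, the simulated overlaps of lists of the same sizes, and the alternatives that the closing section names. The slide was removed before any count of probes past the threshold was seen. The labelled replicates share their numbers across layers. Deviations of same-numbered replicates from their layer means correlated at 0.40 to 0.52 for middle and bottom, and at 0.25 to 0.44 for top and bottom. Every pair exceeded 0.1, so the number was taken to pair the samples in these comparisons. The labels state no pairing. On slides 1 and 3, however, same-numbered subarrays of the 2 images shared their spot positions, so the layout pairs them there. Those of slide 2 shared none.

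The processing and test were tested on simulated data, with 8 probes changed in the top layer in each of 20 simulations and 30.6 probes tested on average. In top against middle, 35.0% of the 2-fold and 76.2% of the 4-fold changes were recovered, and 0.885% of unchanged probes were called. In top against bottom these shares were 30.0%, 73.8% and 1.55%. In middle against bottom, where nothing was changed, 0.164% were called. A 4-fold change, which is 2 on the log2 scale, was estimated at 1.66 on average. The simulated channels had independent noise of 1 common SD, no slide effect and no dye bias of single probes. As many probes were raised as lowered. The rates may differ on the real arrays, where these conditions need not hold.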

Results

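The signals of an array of probes for methanotrophic bacteria were compared between the top, middle and bottom soil layers of a methane-oxidising biocover. Methanotrophs are bacteria that use methane as their carbon and energy source, and a biocover is a soil layer in which they oxidise methane before it reaches the air. Each layer was measured in 2 hybridised channels, 1 in Cy3 and 1 in Cy5, with 3 subarrays (the labelled replicates) in each. The comparisons address how the probe signals differ with depth. Which probes, if any, are controls or recognise other organisms is not known here. The shares, Shannon index and Bray-Curtis distance include all 72 probes. Of the 72 probes, 28 gave signal above the detection level in both channels of at least 1 layer and were tested, and 25 of these were above it in all 6 channels. Between 26 and 36 probes per channel were above the level, and 107 to 137 of the 216 spots per channel were called empty. The median background was 191 to 210 intensity units in Cy3 and 101 to 114 in Cy5, and the brightest spot mean of a channel ranged from 3284 to 14889. Among the tested probes, the median SD over the 3 subarrays was 0.08 to 0.22 on the log2 scale, depending on the channel.

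The 10 brightest probes of a channel held 69.5% to 77.0% of its signal. Probe 2 was the brightest in both channels of the middle layer and both channels of the bottom layer, and probe 47 in both channels of the top layer. Probe 2 took 8.24% ± 0.45 of the signal in the top layer, 14.0% ± 1.2 in the middle and 19.3% ± 1.5 in the bottom (SD, n = 3 labelled samples). Its share of the normexp-corrected signal was 16.3% in the middle Cy5 and 11.5% in the middle Cy3 channel, and 18.8% and 19.2% in the bottom Cy5 and Cy3 channels. The normalised intensity of probe 2 did not pass the test in any comparison. Its top minus bottom log2 difference was -0.67 (SE 0.34), with a limma adjusted p of 0.145.

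The middle layer resembled both neighbours more than these resembled each other. Across the 28 tested probes, the Cy3 and Cy5 channels of one layer correlated at Pearson's r of 0.951 to 0.972 (Spearman's rho 0.933 to 0.978), while channels of different layers correlated at 0.726 to 0.923 (rho 0.671 to 0.930). These are correlations across probes, which are not independent replicates. Within slides, where the channels carry different dyes (the images of slide 2 share no spot positions and may be of separate arrays), r was 0.870 for top and middle on slide 1, 0.909 for middle and bottom on slide 2, and 0.726 for top and bottom on slide 3. The Bray-Curtis distance averaged 0.323 ± 0.019 between top and bottom, 0.244 ± 0.036 between top and middle and 0.168 ± 0.024 between middle and bottom (SD over 4 channel pairs each). The channels of one layer lay 0.134 ± 0.029 apart (SD, n = 3 layers). The 4 distances between middle and bottom, from 0.138 to 0.195, spanned the 0.166 between the 2 channels of the middle layer itself, so these layers were not separated by this measure. All 4 distances between top and bottom, from 0.300 to 0.346, exceeded every distance within a layer. The Shannon index of the probe signals was 3.01 ± 0.03 in the top layer, 2.98 ± 0.09 in the middle and 2.88 ± 0.0049 in the bottom (SD, n = 2 channels). An exact permutation test of 2 against 2 channels cannot give a two-sided p below 0.333, and without background correction the bottom layer was no longer the lowest, at 3.45 against 3.43 in the top layer.

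**Figure D1:**
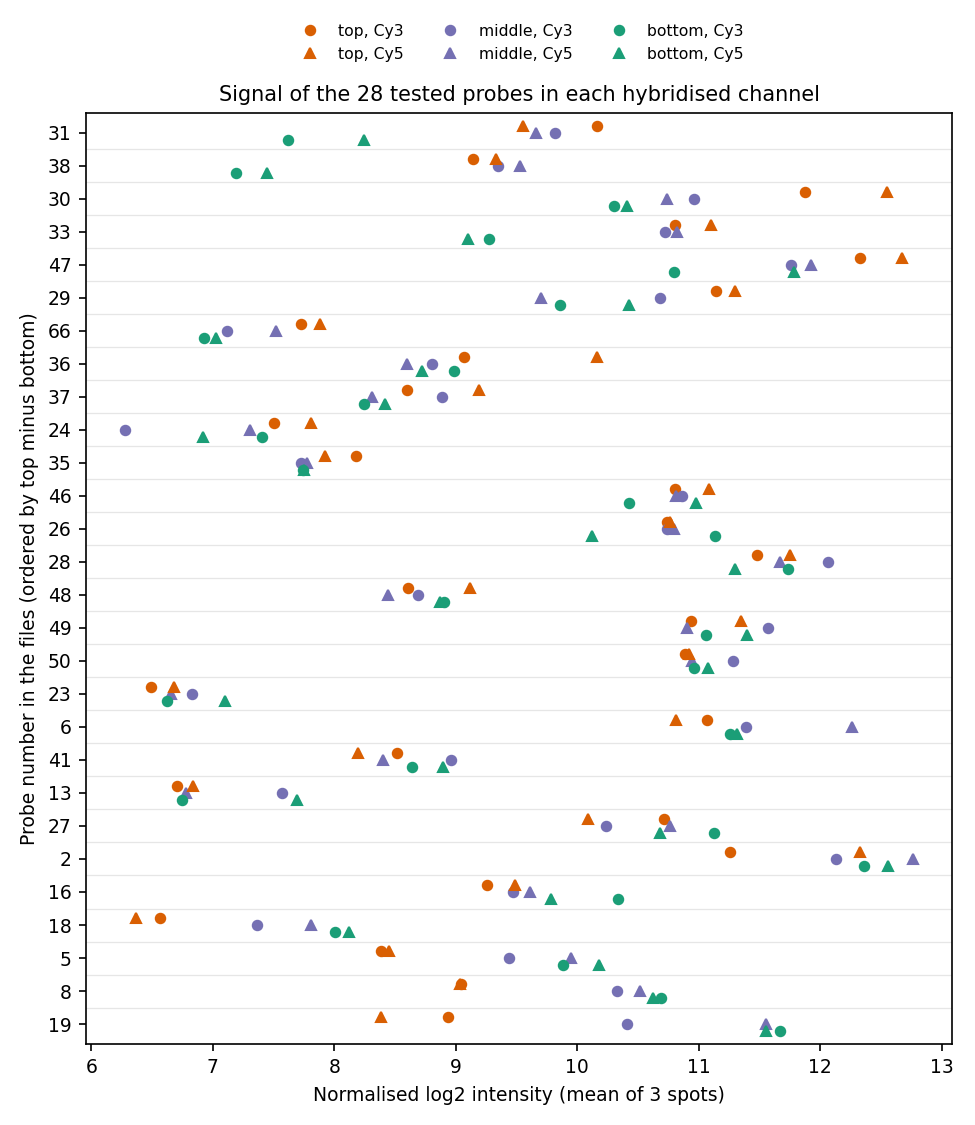
Normalised log2 intensity (horizontal axis) of the 28 tested probes (rows, numbered as in the files and ordered by the top minus bottom difference) in each of the 6 channels; each point is the mean of 3 spots, colour gives the soil layer and shape the dye. For probe 19 (bottom row) both top points lie below all 4 points of the other layers, and for probes 31 and 38 (upper rows) both bottom points lie below the rest.

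Between the top and the middle layer, 5 of the 28 probes passed the test, of which 1 was higher and 4 were lower in the top layer. Probe 19 was 4.99-fold lower in the top layer, and probe 8 was 2.61-fold lower. Probe 30 was 2.57-fold higher in the top layer. The 4 lower probes spanned 2.17-fold to 4.99-fold. For each probe named here and in the other comparisons by its difference, both channels of one layer lay above both of the other. Probe 19 held 1.06% ± 0.17 of the signal in the top layer and 5.63% ± 0.68 in the middle, probe 8 held 1.34% ± 0.03 and 3.50% ± 0.13, and probe 30 held 11.5% ± 0.4 and 4.69% ± 0.43 (SD, n = 3 labelled samples). The top minus middle log2 difference was -2.32 (SE 0.40) for probe 19, with a limma adjusted p of 0.000946. It was -1.38 (SE 0.33) for probe 8 and 1.36 (SE 0.35) for probe 30, with limma adjusted p-values of 0.0105 and 0.0109. Within slide 1, the slide that held both layers, the differences were -2.62, -1.47 and 1.14 in the same order. The other 23 probes differed by up to 2.04-fold without passing the test, and 9 probes had an unadjusted p below 0.05. The channel values of the layers did not overlap for 14 of the 28 probes, where chance gives 33.3%.

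The number of probes past the threshold in this comparison depended on the processing and on single channels. It was 0 without the top Cy5 channel (3 at an unadjusted p below 0.05 in limma), 2 without the top Cy3 channel, 3 without the middle Cy5 channel and 8 without the middle Cy3 channel, and it was 0 when the median replaced the mean over the spots of a probe (5 at an unadjusted p below 0.05). Without the filter on dim probes only 1 probe, probe 8, passed, and probes 30 and 19 did not (limma adjusted p 0.140 and 0.143), with their differences still 1.36 and -2.32. Probe 8 did not pass without the top Cy3 channel (log2 difference -1.42, limma adjusted p 0.0655) or with median centring (-0.74, 0.345), nor did probe 30 without the middle Cy5 channel (1.05, 0.0635). Over their 21 alternatives the adjusted p reached up to 0.411 for probe 30, 0.143 for probe 19 and 0.345 for probe 8. The log2 difference of probe 19 was -1.58 without the middle Cy5 channel and -3.06 without the middle Cy3 channel. With other scalings, 7 probes were higher and 1 lower after median centring and 7 higher and 5 lower as shares of the channel total. Median centring moved the median difference of all tested probes from -0.10 to 0.61 on the log2 scale, so directions are relative to the scaling. With the slide as a random block (correlation 0.455) and no dye term, 4 probes were higher and 6 lower, and with the 3 labelled replicates as samples 8 were higher and 9 lower.

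Between the middle and the bottom layer, 3 of the 28 probes passed the test, and all 3 were higher in the middle layer, by 3.00-fold to 4.35-fold. Probe 38 was 4.35-fold and probe 31 was 3.50-fold higher in the middle layer, on the scale that includes the offset. Probe 38 held 1.66% ± 0.04 of the signal in the middle layer and 0.146% ± 0.016 in the bottom, and probe 31 held 1.76% ± 0.31 and 0.312% ± 0.035 (SD, n = 3 labelled samples). In the bottom layer, 0 of the 3 Cy5 spots of probe 38 were above the detection level, against 3 of 3 Cy3 spots, so the size of its fold depends on the background correction. The middle minus bottom log2 difference was 2.12 (SE 0.33) for probe 38, with a limma adjusted p of 0.000285. For probe 31 it was 1.81 (SE 0.36), with a limma adjusted p of 0.00228. Probe 38 is not among the tested probes when a level of 3 background SDs is required in all 6 channels. Over the 20 other alternatives its difference ranged from 1.43 without background correction to 3.17 with plain subtraction, and that of probe 31 ranged from 1.31 to 2.31 over its 21 alternatives. Between the images of slide 2, which share no spot positions and may be of separate arrays, the differences were 1.91 and 1.58. In this fit 0 probes were lower in the middle than in the bottom layer past the threshold, but 1 was lower under quantile normalisation, with the slide as a random or a fixed block and no dye term, and without the middle Cy5 channel. The largest difference that did not pass was 1.55-fold. The probes with an unadjusted p below 0.05 numbered 3, and channel values did not overlap for 11 of the 28 probes, where chance gives 33.3%. Without the bottom Cy5 or the bottom Cy3 channel, 2 probes passed in either case. Probe 31 did not pass without the bottom Cy3 channel (log2 difference 1.31, limma adjusted p 0.179), without the filter on dim probes (1.81, 0.185) or with the median over spots (1.89, 0.106). Over its 21 alternatives the adjusted p ranged from 2.4e-08 to 0.185. With the 3 labelled replicates as samples 9 probes were higher and 7 lower in the middle layer, 16 in all, and with the replicate number as a block 9 were higher and 8 lower, 17 in all.

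**Figure D2:**
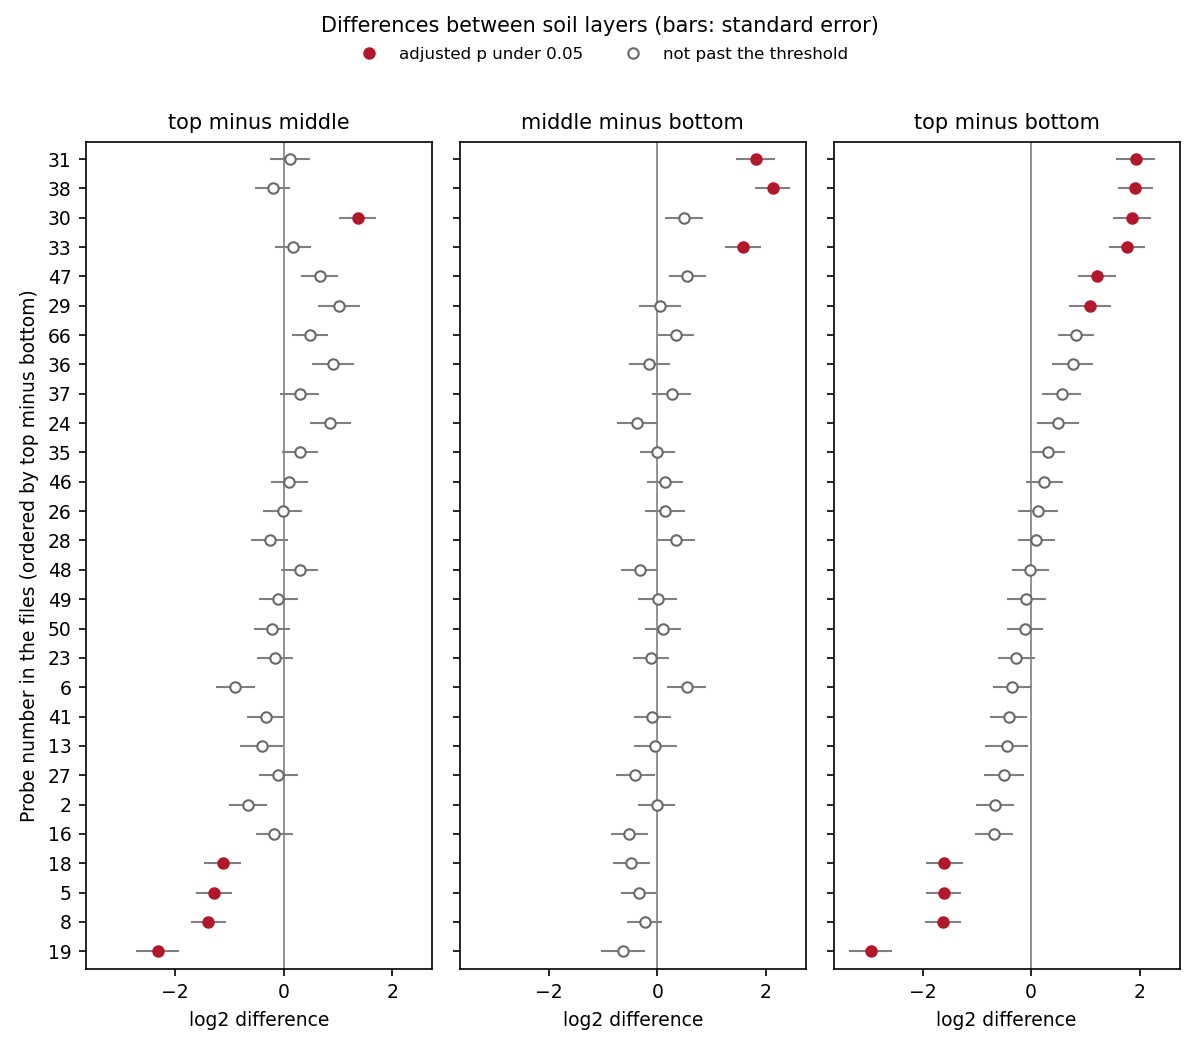
Log2 difference between layers (horizontal axis, with its standard error as a bar) for the 28 tested probes (rows, numbered as in the files) in the 3 comparisons; filled points have a limma adjusted p under 0.05. Filled points number 5, 3 and 10 from left to right, with the largest difference at probe 19 in top minus bottom (-2.95).

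Between the top and the bottom layer, 10 of the 28 probes passed the test, of which 6 were higher and 4 were lower in the top layer. Probe 31 was 3.80-fold and probe 38 was 3.78-fold higher in the top layer, on the scale that includes the offset. Probe 19 was 7.74-fold and probe 8 was 3.07-fold lower in the top layer. The 6 higher probes spanned 2.11-fold to 3.80-fold and the 4 lower probes 3.03-fold to 7.74-fold. The share of probe 31 was 2.93% ± 0.24 in the top layer against 0.312% ± 0.035 in the bottom, and that of probe 38 was 1.98% ± 0.09 against 0.146% ± 0.016. Probe 19 held 1.06% ± 0.17 in the top layer against 8.20% ± 1.56 in the bottom, and probe 8 held 1.34% ± 0.03 against 3.59% ± 0.22 (SD, n = 3 labelled samples). The top minus bottom log2 difference was 1.93 (SE 0.36) for probe 31 and 1.92 (SE 0.33) for probe 38, with limma adjusted p-values of 0.000510 and 0.000428. In the bottom layer 0 of the 3 Cy5 spots of probe 38 were above the detection level. That probe is not tested when a level of 3 background SDs is required in all 6 channels, and over the 20 other alternatives its difference ranged from 1.30 without background correction to 3.17 with median centring, while that of probe 31 ranged from 1.42 to 3.14 over its 21 alternatives. For probe 19 it was -2.95 (SE 0.40), with a limma adjusted p of 6.2e-05 and a range from -3.48 without the top Cy3 channel to -2.23 with median centring over its 21 alternatives, and for probe 8 it was -1.62 (SE 0.33), with a limma adjusted p of 0.000817. Within slide 3, which held both layers, the differences of probes 31, 38, 19 and 8 were 1.93, 2.14, -3.29 and -1.66. Channel values did not overlap for 20 of the 28 probes, where chance gives 33.3%, and 11 probes had an unadjusted p below 0.05. Median centring gave 10 higher and 1 lower probe in the top layer, and under it probe 8 did not pass (log2 difference -0.75, limma adjusted p 0.287, against 2.5e-08 to 0.287 over all its alternatives). With no dye term, 9 probes were higher and 6 lower in the top layer with the slide as a random block, and 8 higher and 6 lower with it as a fixed block. With the 3 labelled replicates as samples 21 probes passed, and 23 passed with the replicate number as a block.

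The probes past the threshold fell into sets shared between comparisons. All 4 probes lower in the top than in the middle layer were also lower in the top than in the bottom layer. Independent lists of these sizes would share 0.571 probes. Lists of the same sizes, taken by rank from 1000 simulations of unchanged layers in the same channels, shared 1.5 probes on average and all 4 in 6 simulations. Probes past the threshold in those simulations were so few that they shared 0.001 on average. All 3 probes lower in the bottom than in the middle layer were also among the 6 lower in the bottom than in the top layer, where independent lists would share 0.643. Simulated lists of the same sizes shared 1.57 on average and all 3 in 123 of the 1000 simulations, so this overlap was not larger than the shared channels can give. Part of either overlap may come from the shared channels. The simulated noise was independent between probes, so the simulated overlaps leave out probes that vary together. Slides 1 and 3 hold different channels of the top layer, and slides 2 and 3 different channels of the bottom layer. For the 4 probes, the top minus other log2 difference closest to 0 was -1.25 on slide 1 and -1.43 on slide 3. For the 3 probes, the bottom minus other difference closest to 0 was -1.58 on slide 2 and -1.83 on slide 3. The sets were chosen from these same channels, so the split by slide is no separate test. The 4 probes low in the top layer, among them probes 19 and 8, together held 3.64% ± 0.26 of the signal in the top layer, 11.8% ± 0.8 in the middle and 14.8% ± 2.1 in the bottom. The 3 probes low in the bottom layer, among them probes 31 and 38, held 9.71% ± 0.52 in the top layer, 7.99% ± 0.15 in the middle and 1.71% ± 0.04 in the bottom. The other 3 probes that were higher in the top than in the bottom layer, among them probe 30, held 31.0% ± 0.4, 16.4% ± 0.1 and 13.9% ± 0.6 (SD, n = 3 labelled samples). The sets were formed from the test on these channels, so their shares are not independent evidence of the directions.

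**Figure D3:**
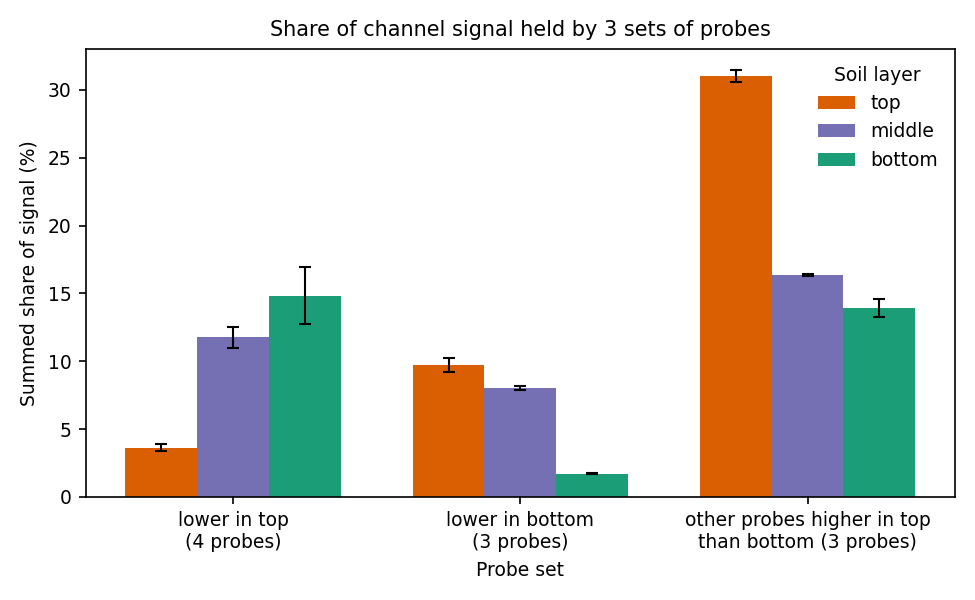
Summed share of the background-subtracted channel signal (vertical axis, in percent) of 3 sets of probes in the top, middle and bottom layers. Bars are means over the 3 labelled samples. Error bars are their SD, which leaves out the spread between the 2 channels of a layer. The set low in the top layer rises from 3.64% to 14.8% in the bottom, and the set low in the bottom layer falls from 9.71% to 1.71%.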

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

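The direction of the 9 differences reported for named probes held in all 187 recomputed values. In 172 of them the limma adjusted p stayed under 0.05. Many of these values repeat the reported difference by construction. Settings that change only the probe filter, the dye term or a channel of the uncompared layer leave it as it is. A slide block moves it: for probe 19 in top minus bottom, from -2.95 to -3.23 with the slide as a random block. Fits with the labelled replicates as samples take their p-values from spots within slides. Neither count therefore measures how far the results would repeat. Probe 38 has no value under the level of 3 SDs in all 6 channels, which leaves it untested and ends both its calls. Of the 15 values whose limma adjusted p was not under 0.05, most were in top versus middle. There the difference of probe 30 ranged from 1.00 to 1.89, that of probe 19 from -3.06 to -1.58 and that of probe 8 from -1.53 to -0.74. Of the settings tried, 4 were chosen after seeing the data: median in place of mean spot intensity, neither dye nor slide term, the slide as a fixed block, and the images of slide 2 as separate slides. In top versus middle, 5 probes passed as reported. The count was 8 with median centring, 12 as shares of the channel total, 1 with no filter on dim probes and 0 with the median over the spots of a probe. It was 10 with the slide as a random block and no dye term, 8 with neither term, 9 with the slide as a fixed block, and 9 with the images of slide 2 as separate slides. With the labelled replicates as samples it was 17 in top versus middle, 16 in middle versus bottom and 21 in top versus bottom. With the replicate number as a block it was 20, 17 and 23, which contained all probes of the reported 5, 3 and 10. The fits on labelled replicates average the same spots as the reported fit, so their differences are the same. Their larger counts rest on the spread between spots within slides, and containing the reported probes is no separate support. In top versus middle, deviations of same-numbered replicates correlated at -0.01 to 0.34, although these shared their spot positions on slide 1. A weak correlation does not undo that layout, and the block moved the count from 17 to 20. Leaving out 1 channel at a time gave 0 to 8 probes in top versus middle, 2 to 4 in middle versus bottom and 7 to 12 in top versus bottom; a layer left with 1 channel was assumed to vary like the others. The Shannon index was 3.43, 3.53 and 3.45 in top, middle and bottom without background correction, and 2.97 in top and 2.81 in bottom with plain subtraction. The Bray-Curtis distance of top and bottom was 0.282 without background correction and 0.299 after quantile normalisation. With no filter on dim probes, mean Pearson's r was 0.982 within layers and 0.953 between layers. The cause of these changes was not tested. Median centring and scaling to the total leave the Shannon index and Bray-Curtis distance as they are. Tests of probe lists and scaling to control probes were not run, because the files name no probes. Signal over background limited the Cy5 channels most, where 26 to 28 probes were above the detection level against 31 to 36 in Cy3.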

Other observations

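The 44 probes left out of the tests were not all dark. Of these, 13 were above the detection level in at least 1 channel, in each case in Cy3 only, and 31 were above it in no channel.

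All tests of explanations in this part were chosen after the results were seen, apart from the splits of the labelled samples. The first pattern is the set of 4 probes lower in the top layer than in both others. Each layer was in both dyes, so a dye bias that is constant for a probe cancels in the layer means by design. All 4 probes kept their direction in both comparisons under the 5 other scalings and background corrections. All 4 were past the threshold in both as shares of the channel total and with plain subtraction. With quantile normalisation, and without background correction, 3 of the 4 were past it in both, and with median centring 1 of the 4. Median centring used the median over all 216 spots of a channel, of which 107 to 137 were called empty, so that median lay near the detection level. The centring moved the set's median top minus bottom difference from -1.62 to -0.81 and that of all tested probes from 0.04 to 0.64. Single tested probes moved by 0.03 to 1.38 in that comparison, and the median SE rose from 0.34 to 0.53. The calls lost under median centring thus went with an uneven shift and a larger spread. The part that the choice of scaling has in the set stays open. A change in the make-up of the methanotroph community with depth may underlie the set, as may a difference between single DNA extracts or labelling reactions, which the design does not separate from the layers.

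The second pattern is the set of 3 probes lower in the bottom layer than in both others. Without the Cy5 image of slide 2, whose spot positions differ from its partner's, their median middle minus bottom difference was 2.16. The difference thus also showed against the bottom Cy3 channel alone. The values had been normalised together with that image before it was left out, and the set was chosen with both bottom channels. The part of that image in the set therefore stays open. All 3 probes of the set stayed past the threshold in both comparisons under the 5 other scalings and background corrections, which argues against the choice of scaling as the whole source. Probes that move together may recognise overlapping target sequences, which was not tested because probe sequences were not used here, so neither set can be read as that many separate organisms. A change of the community with depth and a difference between single extracts also stay open.

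The third pattern is the position of the middle layer between the others. If channels resembled each other mainly because they shared a slide, top and bottom on slide 3 would correlate at least as well as neighbouring layers on different slides. Their r was 0.726, below the 0.819 to 0.923 of neighbouring layers on different slides. Channels of 1 slide also differ in dye. The neighbouring layers on different slides that differ in dye too had r of 0.887 (middle Cy3 and top Cy5) and 0.907 (middle Cy5 and bottom Cy3). Top and bottom channels on different slides had r of 0.78, 0.76 and 0.75, also below all neighbouring layers on different slides. These values argue against the slide as the source of this order. They leave open a resemblance within slides, whose correlation was 0.455 without the dye term. By design each pair of layers also shared 1 slide, so an equal resemblance within every slide could not place the middle layer between the others. A gradual change of the community with depth is consistent with this order, but 3 depths with 2 channels each, from an unstated number of soil samples, leave it a hypothesis.

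With the 3 labelled replicates as samples and only the compared layers in the fit, top versus middle gave 16 probes, middle versus bottom 14 and top versus bottom 23. In each comparison 1 of the 10 splits of the 6 samples, the real one, gave as many, and the highest of the others gave 0, whichever same-numbered replicates they parted. The 10 splits are too few for a share under 0.05. The 6 samples are also subarrays of the same 2 channels per layer, and every other split mixes the layers. Few calls in the other splits were therefore to be expected, whether the layers or only their hybridisations differed. The splits cannot tell these apart.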
